A study of Rattus norvegicus with 8 samples.

How the data were processed

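Gene expression was measured with 1-colour Affymetrix arrays on total RNA from perfused livers of male Wistar rats, an outbred laboratory strain. In liver perfusion, an isolated liver is kept alive by a buffer pumped through its vessels. Per the labels, 4 samples had been perfused with a normoosmotic buffer of 305 mosm/L and 4 with a hypoosmotic buffer of 225 mosm/L, and all 8 carry the time point of 120 min. A buffer of low osmolarity draws water into cells and swells them. Nothing in the labels says whether the 4 samples of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

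RNA was extracted with Trizol and labelled with biotin by the manufacturer's protocol, per the labels' protocols. Transcriptome Analysis Console version 4.0 is named per the submitters' processing notes. The algorithm that summarised probes into probe sets, the background step and the normalization between arrays are not given in the sources used here. The deposited table holds log2 expression values with 2 decimals for 27596 probe sets on 8 arrays, and the authors' values were used as deposited. That they are on the log2 scale was read from their range. The array medians lay between 4.05 and 4.16 log2 units, and the values spanned 0.88 to 13.26. An array has no read depth, and the precision of each mean is limited by the 4 arrays per group. No detection call was used, so a low value can be background, and differences between dim probe sets are compressed.

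Probe sets were named through the platform annotation. Of the 27596 probe sets, 15310 had exactly 1 gene symbol, 323 had several and 11963 are unnamed here. Symbols were updated through the gene ID with the RefSeq gene table of the GRCr8 assembly, in which 15279 of the 15310 matched and 31 did not. For the 527 genes with more than 1 probe set, the probe set with the highest mean over the 8 arrays was taken, which gave 14506 genes. No gene was removed for low signal. No genomic positions are given, because the sources used here name no genome build.

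Hypoosmotic and normoosmotic samples were compared with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes with the default prior, group as the only term, two-sided). P-values were adjusted with the Benjamini-Hochberg method over the 14506 genes, and a gene was called at an adjusted p under 0.05. Changes are given as log2 of hypoosmotic over normoosmotic, with standard errors and 95% confidence intervals from the same fit. Gene lists were tested with camera of limma at its preset correlation between genes of 0.01, adjusted over 43 lists with at least 5 measured members. Of these, 35 were pathways of osmotic and liver physiology and 8 were markers of cell types in whole liver. Camera was repeated with a correlation estimated for each list, and the lists were also tested with fry, a rotation test that does not compare a list with other genes.

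The design, the lists, 12 fixed genes and the rule for named genes were set before the data were examined. The rule took the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap, without uncharacterised or accession-like symbols. It also took the fixed genes, for each called list up to 3 members with the smallest p in its direction and up to 2 called members in the other, and for each other list up to 2 called members. Of the fixed genes, Hspa1b had no probe set with a single symbol and is not analysed here. Genes outside the rule are said to have been chosen after their values were seen. Older symbols in the lists were matched through the synonyms of the RefSeq gene table.

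The fits were tested on simulated data built from the means and spreads of the 14506 genes, in 20 runs with 4 arrays against 4. Of the genes changed by 0.5 log2 units 38.5% were recovered, by 1 unit 99.3% and by 1.5 units 99.9%, and 6.82% of the calls were unchanged genes. A list of 20 genes lowered by 0.3 was called in 100% of runs and 0 unchanged lists were called. The simulated genes varied independently, so that test does not cover correlation between the genes of a list. To cover it, the gene and list tests were repeated on all 35 splits of the 8 arrays into 4 and 4, which allow no two-sided exact p below 0.0286 for a single value.

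Alternatives were a filter on the dimmest 25% of genes, quantile normalization, subtraction of array medians, a trended and robust prior, array weights, the replicate number as a block, the mean over the probe sets of a gene, leaving out each array in turn, and other thresholds. All probe sets in place of named genes were tested as well. A trend on mean expression and gene length was removed, and a clock score was added as a covariate, both chosen after seeing the data. The clock score is the mean log2 value of Bmal1 and Npas2 minus that of Dbp and Per3.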

Results

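Expression profiles of perfused male Wistar rat livers were compared between a hypoosmotic buffer (225 mosm/L) and a normoosmotic buffer (305 mosm/L) after 120 min, with 4 arrays per group. The comparison asks which liver transcripts differ when the perfusate is made hypoosmotic. Values are the deposited log2 expression values, and changes are hypoosmotic minus normoosmotic. The array medians ranged from 4.05 to 4.16, and the number of arrays limits the precision of every value.

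Hypoosmotic perfusion was accompanied by a rise of H1f4 (probe set 10940562), a linker histone gene with related family members. H1f4 rose from 7.59 ± 0.39 to 9.43 ± 0.15 (SD, n = 4 each), a log2 change of 1.84 with a standard error of 0.17. That is 3.59-fold with a 95% interval of 2.78 to 4.63 (limma, adjusted p = 0.000993). The acute phase gene Lcn2 rose by 1.52 ± 0.19 (SE) and Socs3, a feedback inhibitor of cytokine signalling, by 1.33 ± 0.16. Nags, whose product makes the activator of the first urea cycle enzyme, rose by 1.48 ± 0.22, and Angptl4, an inhibitor of lipoprotein lipase, by 1.44 ± 0.16. The importin gene Kpna5 (probe set 10830088) fell by 1.56 ± 0.22, the imprinted noncoding RNA H19 fell by 1.54 ± 0.27, and G0s2, which encodes an inhibitor of adipose triglyceride lipase, fell by 1.39 ± 0.19. Slc38a2, a transporter of neutral amino acids, fell by 1.31 ± 0.17 from a mean of 10.1.

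Among the remaining largest rises, the protease inhibitor genes Serpinb2 and Timp3 rose by 1.55 ± 0.28 and 1.47 ± 0.28, and the chemokine gene Cx3cl1 by 1.25 ± 0.21. Serpinb2 was dim in both groups, at 2.16 ± 0.44 and 3.71 ± 0.62, and lay in the lowest 25% of genes by mean signal. Among the falls, Simc1 fell by 1.15 ± 0.13, Bdp1, a subunit of the initiation factor of RNA polymerase III, by 1.15 ± 0.16, and the small Maf factor gene Maff to 6.00 ± 0.18 from 7.11 ± 0.25 (SD). With Slc5a3, given with the fixed genes, the adjusted p-values of these 16 genes lay between 0.000993 and 0.0196. The rule that picked them required the 4 values of one group to lie beyond the 4 of the other. H19 has another probe set, with a log2 change of −0.93 and an adjusted p of 0.0517 over all probe sets.

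**Figure D1:**
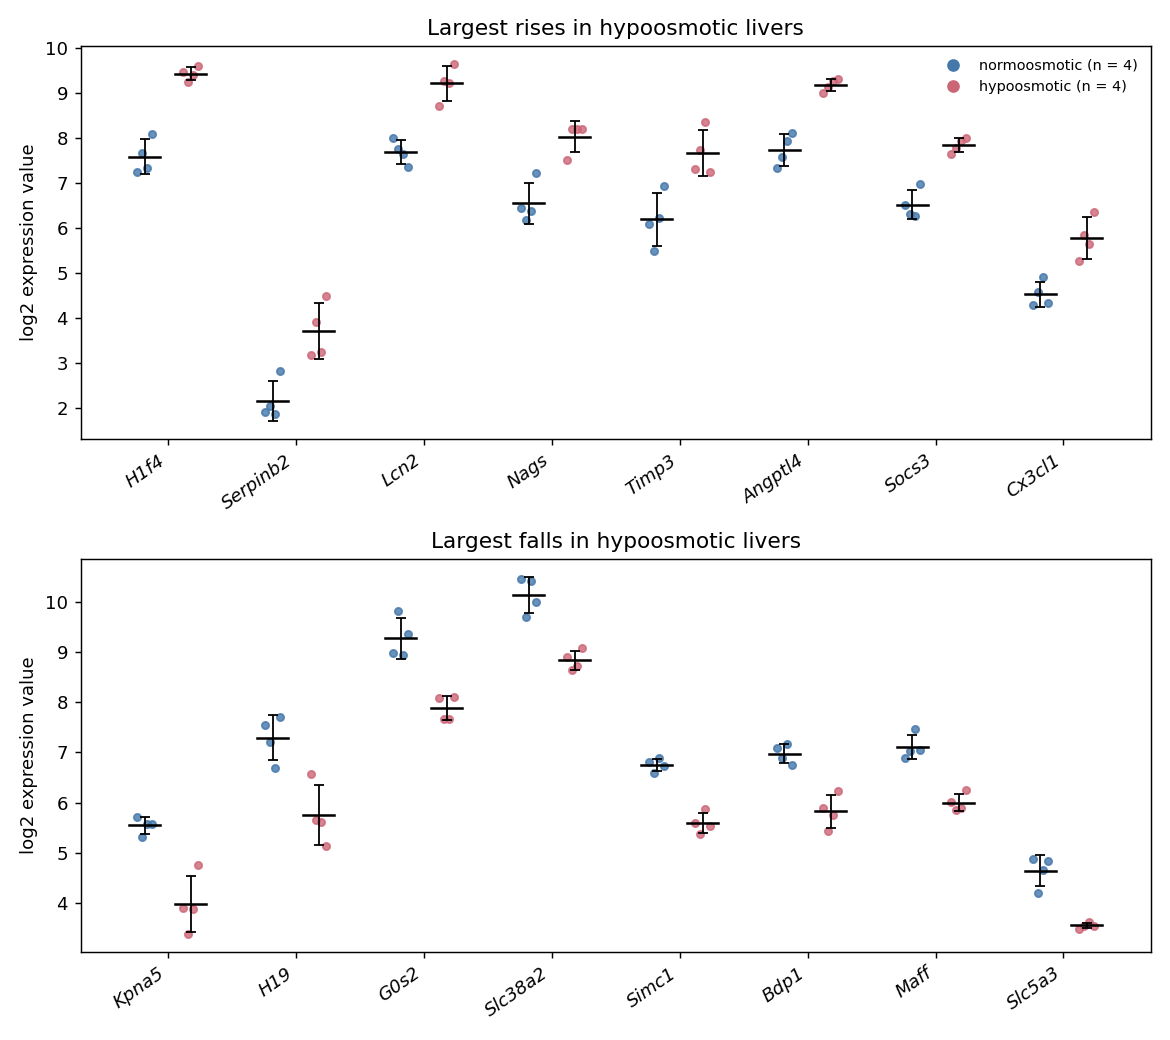
Log2 expression values per array (points), with the group mean (line) and SD (bar), n = 4 per group. The genes are the 8 largest rises and the 8 largest falls among called genes picked for groups that did not overlap. H1f4 values lie between 9.25 and 9.61 in hypoosmotic samples and between 7.25 and 8.10 in normoosmotic samples, and Slc5a3 values between 3.49 and 3.63 and between 4.20 and 4.88.

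Of the 14506 genes, 287 changed at an adjusted p under 0.05 by limma, with 81 higher and 206 lower in hypoosmotic samples. In 283 of them the groups did not overlap. Over all genes, 1199 or 8.27% were apart in this way, where chance gives 2.86%. Changes of at least 2-fold were seen in 31 called genes, of which 16 were higher and 15 lower, and the smallest called change was 0.43 log2 units. The count was 117 without normoosmotic replicate 1, 108 without normoosmotic replicate 3, 155 without hypoosmotic replicate 1, 81 without hypoosmotic replicate 2 and 156 without hypoosmotic replicate 3. With the clock score as a covariate, chosen after seeing the data, it was 92, of which 89 were among the 287. Of 38 called genes picked by a fixed rule, 16 lost the call without hypoosmotic replicate 2 and 15 without normoosmotic replicate 1, Timp3 (adjusted p = 0.0721 and 0.059) and Serpinb2 (0.0633 and 0.0508) among them. Of 35 further called genes, from the lists and from groups chosen after values were seen, 23 and 19 did.

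Of the genes fixed for their known link to osmolarity or cell volume, the osmosensing transcription factor gene Nfat5 (probe set 10807638) fell by 0.94 ± 0.11 (SE), from 6.96 ± 0.07 to 6.02 ± 0.11 (SD, n = 4 each; limma, adjusted p = 0.00159). Slc5a3 (probe set 10750282), the sodium-dependent transporter of the osmolyte myo-inositol, fell from 4.64 ± 0.31 to 3.56 ± 0.06 (adjusted p = 0.00305). The other osmolyte genes did not pass the test, with a log2 change of 0.75 (95% interval 0.07 to 1.43) for the taurine transporter Slc6a6 and 0.29 (−0.09 to 0.67) for aldose reductase, Akr1b1. Slc6a6 ranged from 5.37 to 7.38 over the normoosmotic samples and from 6.85 to 7.14 over the hypoosmotic ones. Odc1, the first enzyme of polyamine synthesis, had a log2 change of 0.77 with an adjusted p of 0.0527, and Pck1, a key enzyme of gluconeogenesis, one of −0.78 with an adjusted p of 0.0963.

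The early response transcription factor genes Jun and Egr1 had log2 changes of −0.55 (adjusted p = 0.0874) and −0.43 (adjusted p = 0.172). For Fos, the kinase gene Sgk1 and the cytoskeletal actin gene Actb the log2 changes were 0.29, −0.21 and 0.31, with 95% intervals that included 0 and adjusted p-values of 0.593, 0.700 and 0.400. Of the 11 fixed genes measured, 2 changed over all genes tested. Adjusted over the list alone, 6 passed, namely Nfat5, Slc5a3, Odc1, Jun, Pck1 and Egr1. Odc1 passed over all genes after quantile normalization (adjusted p = 0.044), with the trended and robust prior (0.0332), with array weights (0.0485) and without the dimmest 25% of genes (0.0469). Jun passed without normoosmotic replicate 1 (0.0495) and Slc6a6 without normoosmotic replicate 2 (0.0301), and Sgk1 had a log2 change of 0.04 without normoosmotic replicate 4.

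The list of ribosome biogenesis and polyamine synthesis was lower in hypoosmotic samples, with a mean log2 change of −0.23 over 26 measured members (camera, adjusted p = 2.42e-06; adjusted p = 0.831 with an estimated correlation). Myc, a transcription factor that drives ribosome production, fell by 0.82 ± 0.12 (SE), the nucleolar GTPase gene Gnl3 by 0.64 ± 0.13 and Nop56, a core protein of small nucleolar ribonucleoproteins, by 0.59 ± 0.13. Wdr43, chosen after its values were seen, fell by 0.46 ± 0.10 and kept its call in 5 of 17 alternatives. These were the 4 members called lower among all genes, and 0 were called higher. Myc kept its call in all 17 alternatives, Gnl3 in 11 and Nop56 in 8. Gnl3 has another probe set, dim at a mean of 2.22, with a log2 change of −0.41 and an adjusted p of 0.113 over all probe sets. Adjusted over the list alone, 11 members were lower and 1, Odc1, was higher. The 11 lower members include 0 polyamine genes, whose log2 changes were 0.77 for Odc1, 0.15 for Srm, 0.05 for Azin1, −0.01 for Amd1 and −0.14 for Sms.

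The immediate early genes were lower as a list of 29 measured members, with a mean log2 change of −0.19 (camera, adjusted p = 0.00467; adjusted p = 0.931 with an estimated correlation). Maff, Myc and Klf6 fell, Klf6 by 0.78 ± 0.14 (SE), as did Dusp1, by 0.88 ± 0.18, and Ier3, by 0.64 ± 0.13, the last 2 chosen after their values were seen. Of 17 alternatives Dusp1 kept its call in 11 (adjusted p up to 0.0799) and Ier3 in 10 (up to 0.0801). In all, 5 members were lower and 0 higher over all genes, against 8 lower and 0 higher adjusted over the list alone. The median change was −0.13, and the uncalled members lay on both sides of 0, between −0.64 for Atf3 and 0.35 for Klf2. Myc is a member of both this list and the list of ribosome biogenesis. Without normoosmotic replicate 4 the list's adjusted p was 0.0549.

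The Nfat5 osmoprotective list was lower, with a mean log2 change of −0.22 and a median of −0.05 over 12 measured members (camera, adjusted p = 0.0376; adjusted p = 0.831 with an estimated correlation). Its called members were Nfat5 itself, Slc38a2 and Slc5a3, all lower, and adjusted over the list alone these were again the 3 that passed, with 0 higher. The remaining 9 members lay between −0.35 for S100a4 and 0.75 for Slc6a6. It was the 1 list called by fry, which tests whether the members move on balance one way (adjusted p = 0.0181). Its adjusted camera p was 0.0541 without normoosmotic replicate 2, 0.0592 without normoosmotic replicate 4, and 0.0961, 0.0538 and 0.0501 without hypoosmotic replicates 1, 3 and 4. It was 0.134 without the dimmest 25% of genes, 0.0541 after quantile normalization and 0.0635 both after subtraction of array medians and with the mean over probe sets. It was 0.0628 with the replicate number as a block and 0.0612 after removal of the trend.

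The heat shock list was lower, with a mean log2 change of −0.18 over 18 measured members (camera, adjusted p = 0.00776; adjusted p = 0.931 with an estimated correlation). Hsf1, the transcription factor of the heat shock response, fell by 0.69 ± 0.12 (SE), the Hsp90 cochaperone gene Chordc1 by 0.92 ± 0.19 and the chaperone gene Hsp90aa1 by 0.48 ± 0.11. These were the 3 members called, all lower, and adjusted over the list alone 5 were lower and 1, Hspb1, was higher. The median change was −0.11, and the uncalled members lay between −0.55 for Dnajb4 and 0.67 for Hspb1. Among them were Hspa8 at −0.125 and Dnajb1 at 0.005. Without hypoosmotic replicate 3 the list's adjusted p was 0.0538, and the call of Hsp90aa1 was lost without any 1 of the 8 arrays, with adjusted p-values up to 0.134. Chordc1 kept its call in 11 of 17 alternatives, with adjusted p-values up to 0.0908, and Hsf1 in all 17.

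The circadian clock list was lower, with a mean log2 change of −0.20 over 16 measured members (camera, adjusted p = 0.0214; adjusted p = 0.931 with an estimated correlation). The clock repressor gene Nr1d2 fell by 0.78 ± 0.17 (SE; adjusted p = 0.0318) and was the 1 member called (adjusted p = 0.111 without hypoosmotic replicate 2 and 0.0735 with the clock score as a covariate), while Per1 and Cry2 had changes of −0.70 (adjusted p = 0.111) and −0.49 (adjusted p = 0.156). Adjusted over the list alone, 2 members were lower and 0 higher. The members did not all move one way. Bmal1 and Npas2 had log2 changes of 0.82 and 0.70, against −0.503 for Dbp and −0.635 for Per3, none of them called. Clock genes also differed between samples of one group. Bmal1, an activator of the clock, read 4.85, 7.18, 4.75 and 7.32 in normoosmotic replicates 1 to 4, and Dbp, which the clock activator drives, 8.89, 6.22, 9.04 and 6.31. In hypoosmotic samples Bmal1 lay between 6.42 and 7.15 and Dbp between 5.96 and 8.08. The list's adjusted p was 0.125 without hypoosmotic replicate 2, 0.0541 after quantile normalization, 0.0586 after subtraction of array medians, 0.0582 after removal of the trend and 0.0785 with the clock score as a covariate.

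The interferon-stimulated list was higher, with a mean log2 change of 0.43 over 20 measured members (camera, adjusted p = 0.00467; adjusted p = 0.931 with an estimated correlation). By limma 0 members passed over all genes, and 6 had an unadjusted p under 0.05, as did 2113 of all 14506 genes. Adjusted over the list alone 1 was higher, the antiviral gene Rsad2, and 0 were lower. Rsad2 had a log2 change of 1.75 with a standard error of 0.42 (adjusted p = 0.0539), Oasl one of 0.58 (0.155) and Rig1, a sensor of viral RNA, one of 0.48 (0.130). Rsad2 ranged from 6.12 to 7.97 in normoosmotic samples and from 7.43 to 9.58 in hypoosmotic ones. Rsad2 passed over all genes without normoosmotic replicate 3 (adjusted p = 0.0302), without hypoosmotic replicate 1 (0.0149) and without the dimmest 25% of genes (0.0479). It also passed with the replicate number as a block (0.00112). The list's adjusted p was 0.0568 without normoosmotic replicate 2 and 0.0896 without hypoosmotic replicate 3. Macrophage markers, measured as a list in the same samples, had a mean log2 change of 0.14 (adjusted p = 0.298).

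In total 6 of 43 lists were called by camera at its preset correlation, 1 higher and 5 lower, and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05. Of the 35 splits of the 8 arrays into 4 and 4, 29 gave at least 6 lists. A camera p as small as the real one came up in 1 split, the real one, for the Nfat5 osmoprotective list and for the heat shock list, in 3 splits for ribosome biogenesis, 6 for the circadian clock, 9 for immediate early genes and 14 for interferon-stimulated genes.

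**Figure D2:**
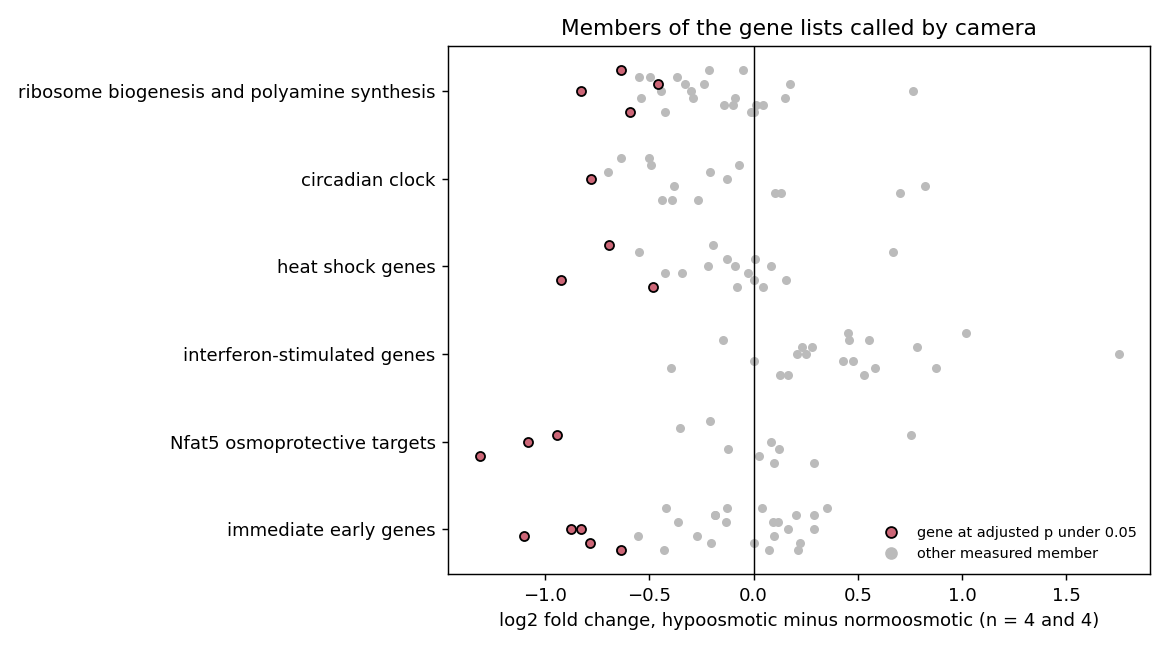
Log2 fold change, hypoosmotic minus normoosmotic, of each measured member (point) of the 6 lists called by camera, with genes at an adjusted p under 0.05 in red, n = 4 arrays per group. The immediate early list has 5 such members and the interferon-stimulated list 0, and its Rsad2 lies at 1.75.

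Among the 29 pathway lists that were not called, 17 held genes that changed. In the list of gluconeogenesis and fasting genes (adjusted p = 0.206) Tat, which starts tyrosine breakdown, fell by 0.76 ± 0.11 (SE), the hepatic binding protein gene Igfbp1 by 0.66 ± 0.10 and Pdk4, an inhibitor of pyruvate oxidation chosen after its values were seen, by 0.87 ± 0.18. Adjusted over the list alone, 5 of its members were lower and 0 higher. The list of genes repressed by insulin through FoxO factors (adjusted p = 0.0809) shares Igfbp1 and Pdk4 and held also Fbxo32, which fell by 0.66 ± 0.11, and Bcl6, chosen after its values were seen, which rose by 0.62 ± 0.13. Of 17 alternatives Pdk4 and Bcl6 each kept the call in 11, with adjusted p-values up to 0.102 and 0.0858. The call of Bcl6 was lost after subtraction of array medians (0.0516), with the clock covariate (0.0649) and without each of 4 arrays in turn. Adjusted over the list alone, 7 of its members were lower and 1 was higher. It was called lower with the trended and robust prior (adjusted p = 0.0449), without normoosmotic replicates 1 (0.0398) and 3 (0.0374) and with the clock score as a covariate (0.03). Of the glucocorticoid-induced genes (adjusted p = 0.581) 4 rose, among them Angptl4 and Lcn2, and 3 fell, among them Tat, against 7 and 5 adjusted over the list alone. The rises of Ddit4 and of Cebpd, chosen after its values were seen, kept the call in 12 and 6 of 17 alternatives. The falls of Dusp1 and Pdk4 kept it in 11 each.

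In the list of bile acid synthesis and transport (adjusted p = 0.0768) the canalicular export pump gene Abcc2 fell by 0.70 ± 0.11 (SE) and Cyp7b1, an enzyme of the alternative bile acid pathway, by 0.78 ± 0.16, and the same 2 passed adjusted over the list alone. It was called lower with the trended and robust prior (0.0449) and without normoosmotic replicates 2 (0.0134) and 3 (0.0259). Of the urea cycle and amino acid catabolism genes (adjusted p = 0.201) Nags rose and Tat fell, against 4 higher and 1 lower adjusted over the list alone. Among plasma proteins and acute phase genes (adjusted p = 0.253) Lcn2 and Socs3 rose, and 4 were higher and 0 lower adjusted over the list alone. In the NF-kappaB and cytokine list (adjusted p = 0.0514) Irf1 rose by 0.67 ± 0.14 and kept its call in 10 of 17 alternatives. Of the list's members 2 were higher and 5 lower adjusted over the list alone. That list was called lower with the trended and robust prior (0.0283), with array weights (0.0379), without normoosmotic replicate 4 (0.0252) and without hypoosmotic replicates 2 (0.00941) and 4 (0.038).

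The glucose transporter gene Slc2a1 rose by 0.95 ± 0.14 (SE) and belongs to both glycolysis (adjusted p = 0.336; 2 higher and 1 lower adjusted over the list alone) and hypoxia-induced genes (adjusted p = 0.902; 3 higher and 2 lower). Angptl4 was the 1 changed gene of fatty acid oxidation and ketogenesis (adjusted p = 0.284; 1 higher). Slc38a2 was the 1 changed amino acid transporter (adjusted p = 0.625; 1 higher and 2 lower over the list alone). It also stood in the Atf4 and amino acid response list (adjusted p = 0.519; 1 higher and 2 lower), in which the growth inhibitor gene Ddit4 rose by 0.66 ± 0.13. Herpud1, a gene of the unfolded protein response (adjusted p = 0.252; 1 higher and 1 lower), fell by 0.67 ± 0.14, and Sqstm1, an autophagy receptor gene (list adjusted p = 0.188; 1 lower), by 0.54 ± 0.11.

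Tagln2, an actin-binding protein gene of the SRF and actin cytoskeleton list (adjusted p = 0.902; 2 higher and 1 lower adjusted over the list alone), rose by 0.77 ± 0.15 (SE). The stress kinase gene Mapk8 fell by 0.67 ± 0.13 in the list of integrins, Src and MAP kinases (adjusted p = 0.558; 1 lower). Pmaip1, a pro-apoptotic p53 target (list adjusted p = 0.395; 3 higher and 2 lower), rose by 0.78 ± 0.16.

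The 12 pathway lists without a changed member had the following adjusted p-values. They were 0.978 for cell volume regulation channels and transporters, 0.902 for fatty acid synthesis, 0.253 both for cholesterol synthesis and for cytochrome P450 and phase 2 enzymes, 0.758 for Nrf2 targets and 0.654 for YAP and TAZ targets. They were 0.645 for cytosolic ribosomal proteins, 0.440 for nuclear-encoded respiratory chain subunits and 0.623 for the proteasome, the cell cycle and pericentral and periportal hepatocyte genes. Adjusted over the list alone, 1 cell cycle gene was higher, 1 pericentral gene was higher and 1 lower, and 1 periportal gene was higher and 2 lower. Leaving out 1 array brought 6 more calls of pathway lists. They were cytochrome P450 higher without normoosmotic replicate 1 (adjusted p = 0.0451), fatty acid oxidation higher without normoosmotic replicate 3 (0.0431), cholesterol synthesis lower without normoosmotic replicate 4 (0.0287), the urea cycle higher without hypoosmotic replicate 1 (0.0308), and gluconeogenesis (0.0295) and autophagy (0.0148) lower without hypoosmotic replicate 4. In 9 lists, none of them called in the full set, the mean or the median change had the other sign than the test, among them fatty acid synthesis, hypoxia-induced genes and gluconeogenesis.

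Markers of the cell types of whole liver were not called as lists. The adjusted p-values were 0.298 for macrophages and for cholangiocytes, 0.519 for sinusoidal endothelium and for lymphocytes, 0.902 for stellate cells and for neutrophils, 0.253 for erythroid genes and 0.664 for hepatocytes. In these 8 lists 0 of 103 measured members were called by limma, over all genes or adjusted over the list alone. An unadjusted p under 0.05 was seen for 8 of the 103, and for 2113 of all 14506 genes. Without normoosmotic replicate 4 the macrophage and sinusoidal endothelial lists were called higher, with adjusted p-values of 0.0252 and 0.0163.

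The samples separated by buffer on the first principal component of the gene table, which held 28.8% of the variance. The normoosmotic samples lay between −19.2 and −7.26 and the hypoosmotic ones between 4.54 and 19.8. The second component, with 18.8%, did not separate the buffers. Correlations between arrays ran from 0.988 to 0.991 within groups and from 0.983 to 0.991 between groups. No pair of arrays held the same values, the closest pair sharing 1.93% of probe set values.

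**Figure D3:**
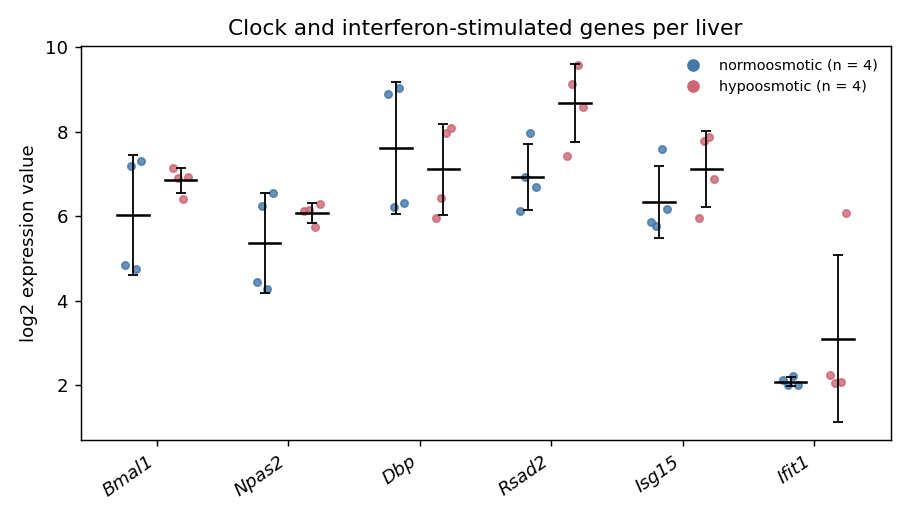
Log2 expression values per array (points) of 3 clock genes and 3 interferon-stimulated genes chosen after their values were seen, with the group mean (line) and SD (bar), n = 4 per group. Bmal1 ranges from 4.75 to 7.32 within the normoosmotic group, and Ifit1 is at 6.07 in hypoosmotic replicate 4 and at most 2.24 in the other samples.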

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

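Tests chosen only after the result was seen were the exact test of the clock score, the exact test of the interferon list mean and the split counts of single lists and tests, by which a camera p that stayed small is judged. The tests of splits of all 8 arrays, of single samples, of macrophage markers, of random covariates and of histone genes were set before their results were seen, except the interval of the histone mean. So was the test with the clock score as a covariate, though the score was chosen after clock values were seen.

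In 5 of 106 groups of 4 values that were tested for a sample far from the others, 1 sample stood apart, and chance gives about 1 in 20. Nags was at 7.51 in hypoosmotic replicate 1 against 8.21 in the other 3. Nfat5 was at 6.86 in normoosmotic replicate 3 against at least 6.98 in the others, and Mapk8 at 5.91 in hypoosmotic replicate 2 against 6.14 to 6.17. Sgk1 was at 8.64 in normoosmotic replicate 4 against 7.58 to 7.73. Ifit1, chosen after its values were seen, was at 6.07 in hypoosmotic replicate 4 against 2.05 to 2.24.

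The report's comparisons leave out probe sets that are unnamed here, and 113 of them changed over all probe sets, 35 higher and 78 lower. The largest rises were those of probe set 10897543, by 2.62 ± 0.22 (SE; adjusted p = 0.000676), above that of any named gene in the report, and of 10761047, by 1.86 ± 0.25 (adjusted p = 0.00514). Probe set 10714830 fell by 2.42 ± 0.29 (adjusted p = 0.00352), more than any named gene in the report, and 10861654 fell by 1.54 ± 0.23 (adjusted p = 0.00878), though its signal was dim, at means of 3.79 and 2.25. Their genes are not analysed here.

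Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, called as many as 287 genes, and the highest of the other splits called 2. Chance assignment of the samples to groups is thus unlikely for the gene count, though 1 of 35 is the smallest share possible. The other splits mix both buffers, so the gap between 287 and 2 does not measure the strength of evidence. For the lists chance assignment cannot be excluded. At least the real number of 6 lists was called in 29 of the 35 splits, and the highest of the others called 14. With an estimated correlation the other 34 splits called 0 lists, as did the real one. The smallest share, 1 of 35, was reached by 2 of the 43 lists, the Nfat5 osmoprotective list and the heat shock list, where chance gives 1.23 lists.

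The fall of the circadian clock list may come from samples at different clock phases. With the clock score as a covariate the 12 members outside the score had a camera p of 0.000864, but a p as small came up in 3 of the 35 splits fitted with that covariate, so the kept p does not exclude it. The clock score differed between groups by 1.33, with an exact permutation p of 0.4, and spanned 4.88 within the normoosmotic group, so a difference in phase between the groups stays open as well. Of 100 random covariates with the same correlation to the groups, 4% left as few genes as the 92 left by the clock score (exact 95% interval 1.1% to 9.93%; median 181 genes), so whether any covariate costs as many calls cannot be told apart from a loss through clock phase. An effect of the buffer on clock genes remains open and untested.

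The rise of the interferon-stimulated list may reflect the spread between samples, since the per-array list mean differed by 0.43 with an exact permutation p of 0.143 (SD 0.32 and 0.38 within groups). That exact test took no account of the replicate numbers. As deviations from each gene's mean, the list means were −0.408, −0.477, 0.234 and −0.212 in normoosmotic replicates 1 to 4. In hypoosmotic replicates 1 to 4 they were −0.267, 0.4, 0.62 and 0.109, higher at every replicate number. Whether the numbers pair the samples is open, and if they do, the exact test cannot decide on the spread. Without each array in turn the highest camera p of the list was 0.0292. The highest p was as small in 8 of the 35 splits when each lost every array in turn, so a single sample is not excluded as the source of the rise. With the macrophage marker mean as a covariate the camera p was 0.000991, a value reached in 14 of the 35 splits fitted with that covariate, so more macrophages are not excluded either. A response of liver cells to the buffer also stays open.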

How the results depend on the processing

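The trend removal and the clock covariate were chosen after seeing the data. Of 38 called genes picked by a fixed rule, 21 kept their call and direction in all alternatives that could test them. The other 17 kept their direction and lost the call in at least 1, with highest adjusted p-values of 0.134 for Hsp90aa1, 0.125 for Nop56, 0.117 for Irf1, 0.111 for Nr1d2, 0.106 for Pmaip1, 0.0981 for Herpud1, 0.0908 for Chordc1, 0.0899 for Sqstm1, 0.0827 for Gnl3, 0.0783 for Cyp7b1, 0.0768 for Ddit4, 0.0724 for Tagln2, 0.0721 for Timp3, 0.0718 for Mapk8, 0.0633 for Serpinb2 and 0.0558 for H19 and Fbxo32. Of the 38, 16 lost the call without hypoosmotic replicate 2, 15 without normoosmotic replicate 1, 13 without normoosmotic replicate 3, 11 and 9 without hypoosmotic replicates 3 and 1, 4 each without normoosmotic replicate 2 and hypoosmotic replicate 4, and 3 without normoosmotic replicate 4. The clock covariate ended 15 of these calls. Of 35 further called genes, from the lists and from groups chosen after values were seen, 10 kept the call in all alternatives and 25 lost it in at least 1, with highest adjusted p-values of 0.151 for Cdk13, 0.147 for Wdr43, 0.127 for Clk4 and Kdm6b and 0.124 for Cebpd, and 0 changed direction.

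With 1 array left out, 81 to 365 genes were called, 25 to 100 higher and 56 to 287 lower, and 3 to 9 lists, 0 to 3 higher and 3 to 7 lower. Fewer samples are part of each such setting. The clock covariate left 92 genes, 28 higher and 64 lower. At an adjusted p under 0.1 there were 601 genes, 179 higher and 422 lower, and at a fold change of at least 2 with an unadjusted p under 0.05 there were 37, 20 higher and 17 lower. Estimated correlation left 0 lists, 0 higher and 0 lower, and fry 1 list, 0 higher and 1 lower. Lower lists numbered 3 after quantile normalization, after subtraction of medians and after trend removal, and 8 with the trended and robust prior, and the cause was not tested.

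Correlations of same-numbered deviations were low but positive, at 0.0456, 0.0276, 0.0835 and 0.173, and not every sample correlated best with its own number. Whether the replicate numbers pair the samples therefore stays open. With the number as a replicate block 256 genes were called, 87 higher and 169 lower, and 5 lists, without the Nfat5 list (adjusted p = 0.0628). With it Rsad2 (0.00112) and Per1 (0.0219) were called, and 3 of the 38 genes, Hsp90aa1 (0.059), Sqstm1 (0.051) and Nop56 (0.0672), and 5 of the 35 were not. Other counts stayed within 1.5 times, among them 349 of all probe sets.

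Some uncalled lists changed sign, at adjusted p-values over 0.05 on both sides, in 52 of 815 list values. The value given is −log10 of the camera or fry p, negative for lower. Without the dimmest 25% of genes it was 0.0563 for fatty acid synthesis, 0.0624 for hypoxia-induced genes and 0.071 for stellate cells. After quantile normalization it was 0.148 for fatty acid synthesis, 0.00065 for Nrf2 targets, 0.162 for hypoxia, 0.0402 for the proteasome, 0.0302 for ribosomal proteins, 0.2005 for stellate cells and 0.0235 for hepatocytes. For cell volume regulation it was −0.00826 with the trended prior, −0.0199 with array weights, −0.0769 with the replicate block and −0.00887 with the mean over probe sets. Array weights gave 0.0329 for fatty acid synthesis and 0.0235 for ribosomal proteins. Fry gave 0.105 for fatty acid synthesis, 0.297 for hypoxia, 0.0188 for stellate cells and 0.028 for neutrophils. Trend removal gave 0.297 for fatty acid synthesis, 0.104 for integrins, 0.19 for hypoxia and 0.196 for stellate cells. The clock covariate gave −0.112 for SRF, 0.00987 for hypoxia, −0.0596 for the cell cycle and 0.0139 for neutrophils.

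With 1 array left out these values ran from −0.555 to 0.143 for Nrf2 targets, −0.469 to 0.652 for SRF, −0.277 to 0.0392 for hypoxia, −0.266 to 0.141 for cell volume regulation, −0.321 to 0.273 for fatty acid synthesis, −0.616 to 0.254 for neutrophils, −0.823 to 0.0829 for YAP and TAZ, −1.64 to 0.8004 for ribosomal proteins, −0.638 to 1.29 for stellate cells, −0.489 to 0.971 for the cell cycle, −0.875 to 0.0652 for pericentral genes, −0.747 to 0.012 for hepatocytes and −0.862 to 0.179 for the proteasome. The log2 change of Sgk1 ran from −0.32 to 0.0383. The cause of these changes of sign was not tested. Signal over background is not given per probe set in the values used, which limits what can be said of the 5 called genes in the lowest 25% by mean signal.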

Other observations

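The groups of genes that follow were chosen after their values were seen, as were the genes named from them, and their camera p-values were adjusted over 9 groups with at least 5 members. Their p-values are therefore no independent evidence, and these groups were not tested on the 35 splits. Over all 14506 genes 81 were called higher and 206 lower, against which the counts per group are to be read. Of 32 measured histone genes, with a median change of 0.17, 5 rose and 0 fell, namely H1f4, H3f3b by 1.05 ± 0.10 (SE), Hist1h4b by 1.05 ± 0.13, Hist1h2bq by 1.05 ± 0.15 and Hist1h2ail1 by 0.73 ± 0.11 (camera, adjusted p = 7.73e-07; adjusted p = 0.0664 with an estimated correlation). The same number rose after quantile normalization and after subtraction of array medians, while with the mean over probe sets Hist1h2ail1 lost the call, with a change of 0.40 and an adjusted p of 0.0868. Many histone genes have near-identical copies, and a probe set can pick up several of them.

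Of 14 kinases, cyclins and regulators tied to transcription 5 fell, namely Hexim1 by 1.06 ± 0.19 (SE), Ccnl2 by 0.76 ± 0.12, Cdk9 by 0.72 ± 0.13, Cdk12 by 0.54 ± 0.12 and Cdk13 by 0.51 ± 0.12 (camera, adjusted p = 7.05e-09; adjusted p = 0.0664 with an estimated correlation), and 4 fell after quantile normalization. Of 17 alternatives the call was kept in 17 for Ccnl2, 14 each for Hexim1 and Cdk9, 8 for Cdk12 and 6 for Cdk13. Of 23 Mediator subunits 4 fell, Med13 by 0.78 ± 0.11, Med1 by 0.73 ± 0.12, Med15 by 0.64 ± 0.13 and Med14 (adjusted p = 0.0031; adjusted p = 0.235 with an estimated correlation). Med14 was dim, in the lowest 25% of genes by mean signal, and kept its call in 9 of 16 alternatives, and Med15 in 13 of 17. Of the 4 CDC-like kinases, which phosphorylate splicing factors, Clk1 fell by 1.02 ± 0.13, Clk4 by 0.64 ± 0.14 and Clk3 by 0.57 ± 0.11, and the group was too small for camera. Of 17 alternatives Clk3 kept its call in 13 and Clk4 in 10. Of 20 nucleoporins 3 fell, among them Nup58 by 0.70 ± 0.11 (adjusted p = 3.33e-05; 0.0664 as the adjusted p with an estimated correlation). Nup58 kept its call in all 17 alternatives, Nup54 in 12 and Nup153 in 9.

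Of 27 RNA-binding motif genes 2 fell, Rbm25 by 0.89 ± 0.13 (SE) and Rbm28 by 0.59 ± 0.12 (camera, adjusted p = 0.000833; adjusted p = 0.162 with an estimated correlation). Of 30 DEAD-box helicases 1 fell, Ddx18 by 0.92 ± 0.17 (adjusted p = 2.73e-07; adjusted p = 0.0664 with an estimated correlation), of 5 chromodomain helicases Chd6 by 0.82 ± 0.13 and Chd1 by 0.66 ± 0.13 (0.00196; 0.0664 with an estimated correlation) and of 13 lysine demethylases Kdm4c by 0.76 ± 0.15 and Kdm6b by 0.58 ± 0.13 (8.16e-05; 0.118 with an estimated correlation). Of 17 alternatives the call was kept in 13 for Ddx18 and Kdm4c, 12 for Chd1 and 10 for Rbm28 and Kdm6b. After subtraction of array medians 2 DEAD-box helicases fell, and after quantile normalization 3 lysine demethylases. Of 137 zinc finger genes 3 fell (adjusted p = 0.855; adjusted p = 0.904 with an estimated correlation), with a mean change of 0.02 that turned to −0.02 after subtraction of array medians. The 3 were Zfp592, Zfp131 and Zfp830, which kept their calls in 13, 11 and 11 of 17 alternatives. All 3 lost the call without normoosmotic replicate 1.

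For the rises among histone genes, a trend of changes with mean expression and gene length was tested as a source. After its removal the mean change of the 32 genes was 0.29 against 0.32 before, with a 95% interval of 0.14 to 0.44 over arrays (Welch, chosen after the result was seen), and all 5 rises were still called. The removed trend thus took up little of that mean change. Because the genes were chosen for their rise, the interval is no independent evidence against the trend as a source. The camera p was 3.48e-08, and 0.0166 with an estimated correlation, on genes chosen for their rise. Whether more cells in S phase contribute cannot be told from 7 measured S phase genes, whose median log2 change was 0.12. Of these 1, Rrm2, had a 95% interval, from 0.39 to 1.23, that reached 1.05, the median rise of the 5 called histone genes. Rrm2 was itself not called (limma, adjusted p = 0.0549). The intervals of Mcm2, Mcm5, Mcm6, Mcm7, Pcna and Tyms ended below that rise. The 5 genes behind it were chosen for their rise, and the median change of all 32 histone genes was 0.17. That lower value lay within the intervals of Mcm2, Mcm5, Mcm6, Pcna and Tyms, above that of Mcm7 and below that of Rrm2. Whether single gene copies or the buffer's effect on histone transcripts are behind the rise was not tested.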
